A study of Macaca fascicularis with 10 samples.

How the data were processed

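RNA was measured in the dorsal part of the spinal cord of 5 cynomolgus macaques (Macaca fascicularis) after SNL surgery. SNL stands for spinal nerve ligation, a model of neuropathic pain in which a spinal nerve is tied off on 1 side. Each animal gave an ipsilateral (right) and a contralateral (left) sample, so that 10 libraries form 2 groups of 5. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a stranded mRNA kit, which selects polyadenylated RNA. No sham-operated or unoperated animal was analysed here.

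The deposited table holds 24148 genes with an RSEM expected count and a TPM value for each library, per the file headers. Per the submitters' processing notes, the tools were fastp 0.22.0, STAR 2.7.9a and RSEM 1.3.1; their parameters, the genome build and the annotation are not given in the sources used here. An expected count is an estimate in which a read that fits several genes is divided between them, so the deposited expected counts need not be whole. Here a count was taken as whole if it lay within 0.005 of a whole number. The TPM values were scaled by the authors to the same sum in each library, and they keep no depth. All 20 value columns matched 1 sample's description each, and 0 columns were left unmapped.

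Genes are given by Ensembl identifiers alone. The reference table for this species pairs no Ensembl identifier with a symbol, and 0 of the 24148 identifiers matched. The 30 gene lists fixed before the data were examined, which covered cholesterol synthesis and transport, fatty acid synthesis, glial, immune, neuronal and vascular markers and pain-related genes, were therefore not tested, and neither were the genes fixed by name. Cell type makeup, blood content and tissue from outside the dorsal cord were not assessed for the same reason, and no coordinates are given.

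Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with side as the group (16143 kept, 8005 removed), libraries were scaled by TMM, and the quasi-likelihood F test (estimateDisp, glmQLFit with robust=TRUE, glmQLFTest) was run with animal as a block and side as the tested term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of F. CPM values are counts scaled to the TMM-adjusted library size, and log2 CPM used a prior count of 2. The choice of a block, the filter, the threshold, the alternatives and the rule for named genes were fixed before the data were examined.

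The pairing comes from the animal numbers in the labels. Deviations of log2 CPM from the mean of each side correlated between the 2 libraries of an animal at r = 0.676 to 0.942, against at most 0.395 between libraries of different animals. No pair of libraries held identical values. A chi-square test was run over genes with at least 20 summed counts. The most similar pair was the 2 sides of animal 5, which differed by 10.0 times the sampling noise per degree of freedom. All 10 libraries were therefore counted separately. The 2 libraries of an animal come from 1 animal, and n = 5 is the number of animals.

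The rule for named genes took, among called genes that moved the same way in 5 of 5 animals and had a symbol, the 12 with the largest log2 fold change in each direction, with further examples from the gene lists. With no symbols, the first part was applied without that condition, and 2 identifiers per direction are given. The gene with the smallest p is given beside them, outside the rule.

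The paired test was tested on simulated data. Counts for the 16143 genes were drawn from the real animal means, library sizes and dispersions, with 200 genes changed. Genes were drawn independently of one another, and a changed gene had the same fold change in all 5 animals. Real genes are not independent and the real animals differ in their side differences, so the shares below need not hold for the real fit. Of the 16009 simulated genes that passed the filter, the test recovered 62% of 50 genes changed 1.3-fold, 76% of 50 changed 1.5-fold, 92% of 50 changed 2-fold and 100% of 49 changed 3-fold, with 8 false calls (4.65% of all calls). The limma test on side differences recovered 98% of 50 genes changed 3-fold, with 10 false calls among 16143 genes. Its recovery of smaller changes was not checked.

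Alternatives were the fit without the block, RLE and upper-quartile scaling, no filter and a stricter filter (over 1 CPM in at least 5 libraries), each animal left out, DESeq2 1.42.0, limma-voom (limma 3.58.1), the non-robust fit, and limma-trend on the deposited TPM as log2(TPM + 1) or log2(TPM + 0.1) over genes above 0 in at least 5 libraries. With a block, leaving out 1 library removes its animal from the comparison, so animals were left out whole. Added after the data were seen were DESeq2 and limma-voom without the block, and limma-trend on the 5 side differences of log2 CPM as they were, with the trend on effective length removed (the ratio of count to TPM, from values of at least 0.5 TPM), and with the 4 axes that separate the animal means removed. The adjusted p-values from edgeR, DESeq2 and limma come from models fitted across all genes.

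Depth was 26539772 to 34997645 expected counts per library, with 15867 to 16312 genes at 10 counts or more. Intervals for shares of genes are exact 95% binomial intervals; genes are not independent, so these are narrower than the true uncertainty. Reads carry no molecular identifiers in the sources used here.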

Results

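The dorsal spinal cord was profiled by RNA-seq on both sides of 5 cynomolgus macaques with a ligated spinal nerve, to find genes that differ between the injured (ipsilateral, right) side and the opposite (contralateral, left) side. The 5 contralateral libraries held 26980910, 29110629, 34997645, 28333471 and 33710951 expected counts in animals 1 to 5, and the 5 ipsilateral libraries 32101171, 26539772, 30814232, 30598994 and 31863245. The ipsilateral library was the deeper one in 2 of 5 animals. Of 24148 genes in the table, 16143 were tested. The series concerns cholesterol metabolism and neuroinflammation; genes of these themes were not analysed here, because the table gives Ensembl identifiers and none was paired with a symbol.

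Animals differed far more than sides. The first principal component of log2 CPM held 72.2% of the variance and set both libraries of animal 3 apart, at scores of 114 (contralateral) and 123 (ipsilateral) against -39.2 to -19.1 in the other 8 libraries. The 10 most abundant genes took 23.8% and 23.9% of the counts in animal 3, and 11.3% to 16.7% in the other animals. The third component, with 6.30% of the variance, was lower on the ipsilateral side in 5 of 5 animals, with a mean difference in score of -11.7 ± 6.83 (SD, n = 5). The difference was -19.2 in animal 1, -16.1 in animal 2, -11.8 in animal 3, -10.2 in animal 4 and -1.24 in animal 5. The two-sided exact sign-flip permutation p was 0.0625, the smallest that 5 animals can give. The ipsilateral side was also higher on the first component in 5 of 5 animals, by 5.82 ± 3.10 (SD, n = 5, exact p = 0.0625), and lower on the fourth (5.38% of the variance) in 5 of 5, with a mean difference of -3.16 ± 0.963 (SD, n = 5, exact p = 0.0625). On the fourth component animal 5 differed by -2.95 and the other animals by -4.81 to -2.27. On the second component (6.37% of the variance) the ipsilateral side was higher in 1 of 5 animals. Its mean difference was -1.54 ± 1.49 (SD, n = 5, exact p = 0.125). Later components were not compared between the sides.

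**Figure D1:**
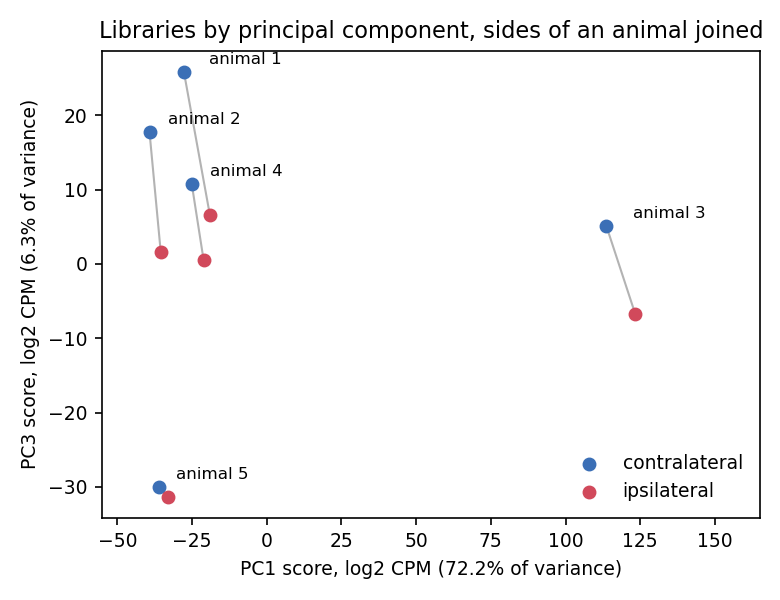
Scores of the 10 libraries on principal components PC1 (x axis) and PC3 (y axis) of log2 CPM, with the share of variance on each axis; points are libraries coloured by side and lines join the 2 libraries of an animal. Both libraries of animal 3 lie above 100 on PC1, and the ipsilateral library lies below the contralateral one on PC3 in 5 of 5 animals, with a difference of -1.24 in animal 5.

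Between the sides, 444 of 16143 genes (2.75%) differed in edgeR's quasi-likelihood test with animal as a block: 364 were higher and 80 lower on the ipsilateral side. The changes were small. Genes that rose had a median log2 fold change of 0.39 (1.31-fold; quartiles 0.28 and 0.53), and genes that fell one of -0.26 (0.833-fold; quartiles -0.34 and -0.22). At least 2-fold changes were found in 17 genes that rose and 5 that fell, and 79 of the 364 and 40 of the 80 changed less than 1.2-fold. All 5 animals moved the same way in 356 of the genes that rose and 76 of those that fell, together 97.3% of the called genes, against 13.3% of all tested genes and 6.25% by chance; the test itself favours such genes. An unadjusted p under 0.05 was reached by 2360 genes (14.6%).

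The calls depended on comparing the sides within animals. The biological coefficient of variation was 7.53% with the animal as a block and 36.6% without it. Without the block, edgeR called 0 genes (193 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 13. With the block, edgeR called 135 genes without animal 1, 196 without animal 2 and 307 without animal 3. It called 206 without animal 4 and 1255 without animal 5. Limma on the deposited log2(TPM + 1), also with the block, called 43. That fit used no TMM scaling and tested 20065 genes, so more than the measure differed. Each of the 444 genes kept its direction wherever it was tested. That could hardly fail, since 432 of them moved the same way in all 5 animals and the settings share the same libraries.

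Genes that fell were more often abundant ones. Of the genes that rose, 43.7% (159 of 364) lay below the median abundance of the tested genes; of those that fell, 18.8% (15 of 80) did (odds ratio 3.35, Fisher's exact test across genes, p = 2.46e-05; genes are not independent replicates). With the tested genes cut into 4 abundance classes of 4035 or 4036, the most abundant class, from 48.7 CPM upward, held 95 genes that rose, with a median log2 fold change of 0.24, and 41 that fell, with a median of -0.24. The least abundant class, up to 4.46 CPM, held 36 that rose, with a median of 0.82, and 8 that fell, with a median of -1.26. In that class 1.09% of genes were called, against 3.22% to 3.37% in the other 3. The medians cover called genes alone, and a scarce gene needs a larger change to be called. They do not show that scarce genes changed more.

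**Figure D2:**
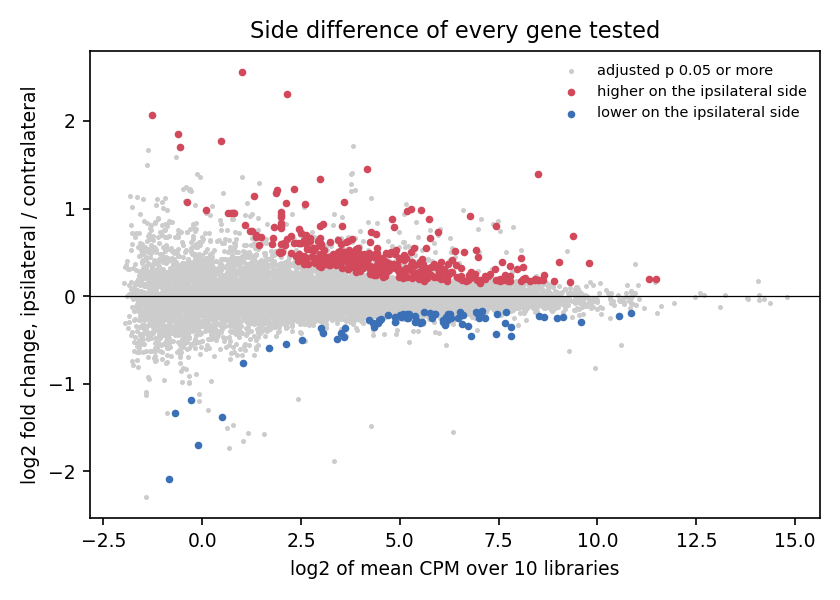
Log2 fold change of the ipsilateral over the contralateral side (y axis) against the log2 of mean CPM over the 10 libraries (x axis) for the 16143 genes tested; coloured points are the 364 genes called higher and the 80 called lower. Most called genes changed less than 2-fold.

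The largest rise among called genes that moved the same way in 5 of 5 animals was that of ENSMFAG00000005215, from 0.603 ± 0.436 CPM on the contralateral side to 3.41 ± 0.711 CPM on the ipsilateral side (SD, n = 5), a log2 fold change of 2.56 ± 0.32 (SE; 5.89-fold; edgeR adjusted p = 0.00279). It had 9 to 39 counts in the contralateral and 69 to 141 in the ipsilateral libraries, all of them whole estimates, and its rise was smallest in animal 3, at 1.03 on the log2 scale, and 2.57 to 3.35 in the other 4. It remained called whichever animal was left out.

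ENSMFAG00000060234 rose from 1.53 ± 1.38 to 7.37 ± 6.45 CPM (SD, n = 5), a log2 fold change of 2.31 ± 0.38 (SE, edgeR adjusted p = 0.0417). Its contralateral library in animal 5 held 0 counts and its highest value was 442 counts on the ipsilateral side of animal 3. Its counts were not all whole, so reads were divided with other genes. The edgeR adjusted p was 0.202 without animal 1, 0.211 without animal 2, 0.122 without animal 3 and 0.118 with no filter on low counts.

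The 2 largest falls, like the largest rise, were in scarce transcripts. ENSMFAG00000036097 fell from 0.871 ± 0.601 to 0.253 ± 0.392 CPM (SD, n = 5), with 11 to 54 counts per contralateral library and 1, 7, 23, 1 and 1 counts in the ipsilateral libraries of animals 1 to 5. The fitted log2 fold change was -2.09 ± 0.44 (SE, edgeR adjusted p = 0.0256), and at 1 count per library its size depends on the model. The adjusted p was 0.109 without animal 1, 0.0808 without animal 2 and 0.0774 without animal 4, and the gene did not pass the filter without animal 3. ENSMFAG00000028239 fell from 1.47 ± 1.56 to 0.374 ± 0.182 CPM (SD, n = 5), a log2 fold change of -1.69 ± 0.36 (SE, edgeR adjusted p = 0.0236). In animal 5 it had 13 contralateral and 12 ipsilateral counts, a difference within counting error. Its counts were not all whole, and its adjusted p was 0.172, 0.0944 and 0.137 without animals 1, 2 and 3. The rule ranked genes by fold change and not by p. The smallest p was that of ENSMFAG00000032157, which the rule did not name and which was more abundant. It rose from 126 ± 14.6 to 219 ± 19.0 CPM (SD, n = 5, edgeR adjusted p = 1.51e-06). Its rise per animal was 0.66 to 0.97 on the log2 scale.

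**Figure D3:**
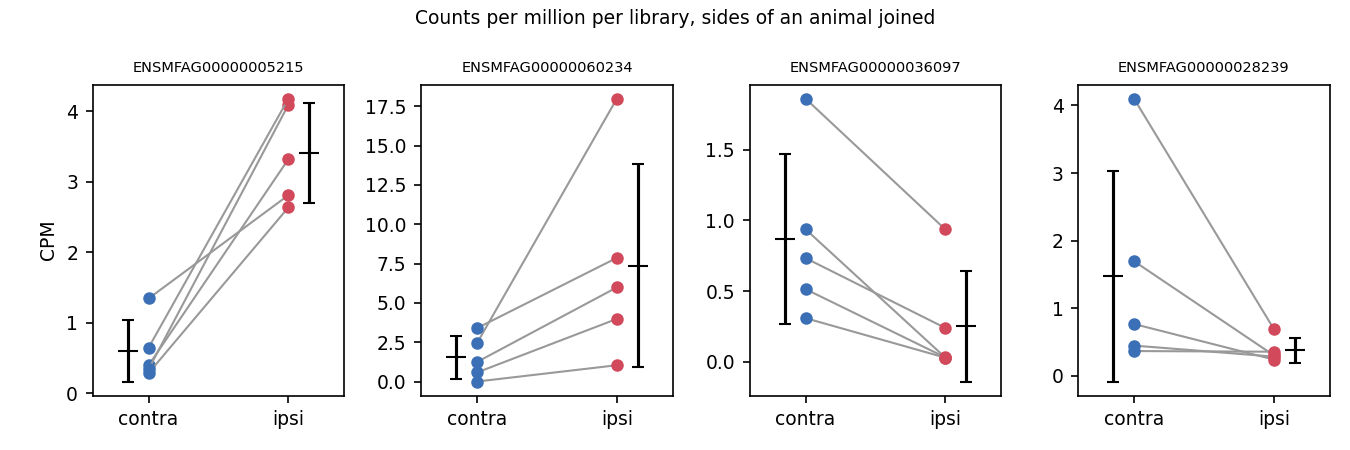
CPM (y axis, linear, a separate scale in each panel) of the 4 named genes in the contralateral and ipsilateral library of each animal, joined by a line; the black bars beside the points give the mean and SD of the 5 libraries of a side. ENSMFAG00000005215 rose in every animal, while ENSMFAG00000028239 had 13 and 12 counts on the 2 sides of animal 5.

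Genes called in 4 animals were then read in the animal left out, which played no part in the call. Of 135 genes called without animal 1, 99.3% moved the same way in animal 1; the share was 99.0% of 196 for animal 2, 90.6% of 307 for animal 3 and 97.1% of 206 for animal 4. Of the lower genes alone, 100% moved the same way in animal 1, 96.6% in animal 2, 74.1% in animal 3 and 88.9% in animal 4. Without animal 5, edgeR called 1255 genes (773 higher and 482 lower), and 53.5% of those moved the same way in animal 5: 68.5% of the higher and 29.3% of the lower genes. Of all tested genes, 50.3% were higher on the ipsilateral side of animal 5. Genes filtered out of the fit to all 5 animals were left out of these shares. The median change in the animal left out, signed by the direction in the other 4, was 0.64 on the log2 scale in animal 1, 0.40 in animal 2, 0.31 in animal 3, 0.41 in animal 4 and 0.02 in animal 5.

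By size of the change in animals 1 to 4, the share moving the same way in animal 5 was 41.4% (95% exact interval 37.3 to 45.7) of 538 genes under 1.2-fold, 62.0% (57.7 to 66.2) of 521 genes from 1.2 to 1.5-fold and 63.9% (56.7 to 70.7) of 194 genes at 1.5-fold or more. The classes differed in their mix of directions. Of the higher genes, 148 of 235, 268 of 361 and 113 of 176 moved the same way in these 3 classes, and of the lower genes 75 of 303, 55 of 160 and 11 of 18. In animals 1, 2 and 4 at least 91.9% of genes moved the same way in each size class, although the class under 1.2-fold held 1 to 9 genes there, and in animal 3 at least 80% did. Of the few lower genes at 1.5-fold or more, 4 of 5 moved the same way in animal 2, 2 of 4 in animal 3 and 2 of 5 in animal 4. Across all tested genes, side differences correlated at r = 0.08 to 0.38 between animals 1 to 4 and at r = -0.05 to 0.04 between animal 5 and each of them; these correlations are across genes, which are not independent replicates.

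**Figure D4:**
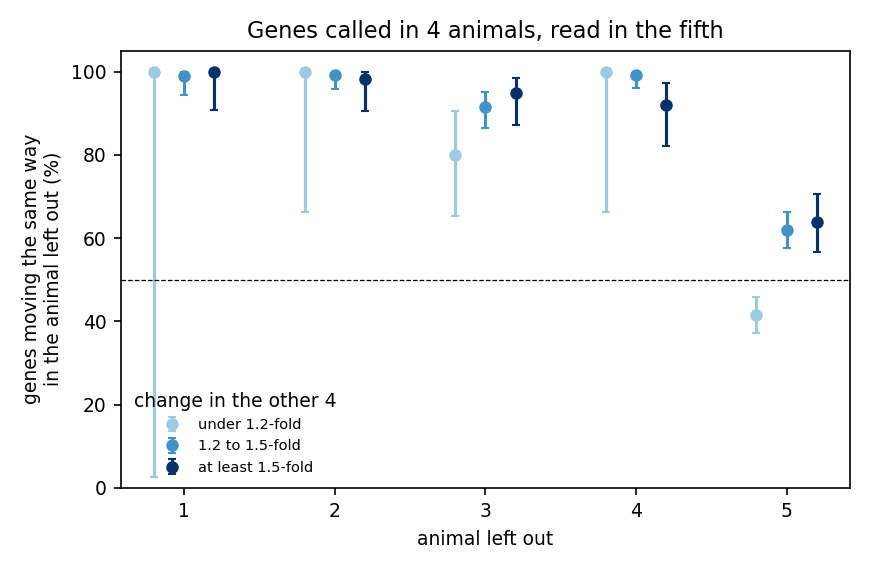
Share of genes, in percent (y axis), that moved in the animal left out (x axis) the same way as in the 4 animals in which they were called, by the size of the change in those 4; bars are exact 95% binomial intervals over genes and the dashed line marks 50%. The shares lie at 80% or more for animals 1 to 4 and between 41.4% and 63.9% for animal 5; the class under 1.2-fold holds 1 gene for animal 1 and 9 each for animals 2 and 4.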

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

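Of the tests below, those on depth, on right against left, on a shift common to all genes and the 3 on animal 5 were chosen after the results were seen; the others were set before. Of 29 groups of 5 values, 9 held a value far from the rest by Dixon's test, where chance gives about 1 in 20 (1.45 of 29). The groups are not independent, since several measure the same libraries in related ways and others are named genes picked for large changes. The 9 are therefore not 9 separate surprises.

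Animal 3 accounted for 7 of the 9. Its first-component scores were 114 (contralateral; next -25.1) and 123 (ipsilateral; next -19.1), its TMM factors 0.830 and 0.798 (next 1.03 on both sides), and its contralateral median TPM over the tested genes 6.25 (next 11.1). The distance of its mean profile from the other animals was 2.37 times the largest distance of another animal. Depth as the cause is argued against, since 1 of its 2 libraries lay within the range of the other 8. Gene length as the whole cause is argued against too, with a ratio of 2.32 after its trend was removed. Without the 100 most abundant genes the ratio was 2.37, but the largest move of any animal's distance was 0.54%, so that test decides nothing. If a few genes took counts from all others alike, most of the distance in CPM without TMM would be 1 common shift; that shift and the 100 most abundant genes together held 16.01% of the squared distance (14.72% and 16.56% in the single libraries), which argues against it as the whole cause. A difference in tissue makeup, dissection or the animal itself stays open and was not tested.

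In the same animal, the ipsilateral CPM of ENSMFAG00000036097 was 0.936 (next 0.240) and that of ENSMFAG00000028239 was 0.692 (next 0.355). The ipsilateral library of animal 2 was the shallowest of its side, with 26539772 expected counts (next 30598994).

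Animal 5 stood apart in the share of genes moving the same way as in the other 4 animals, 53.5% (next 90.6%), and leaving it out raised the number of called genes from 444 to 1255. Swapped sides in its labels stay open: of the genes called in the others, 68.5% of the higher ones moved the same way in animal 5, which goes against a swap, and 29.3% of the lower ones, which goes with it. The 29.3% comes mostly from lower genes that changed by less than 1.5-fold in the others (75 of 303 under 1.2-fold and 55 of 160 from 1.2 to 1.5-fold moved the same way); at 1.5-fold or more, 113 of 176 higher and 11 of 18 lower genes moved the same way, which goes against a swap, though 18 genes are few. Shallow libraries are argued against, since 0 of its 2 libraries were the shallowest of their side. Its side difference correlated with the mean of the other 4 animals at r = 0.026 across genes, against 0.24 to 0.42 for the other animals. This correlation measures agreement with the other animals and not size, and it restates the pattern in part. The SD over genes of the side difference was 0.310 in animal 5 and 0.332 to 0.398 in the others. The values thus show a side difference that animal 5 shared little with the others, and they do not establish a smaller one. Whether that comes from the injury, from its time course or from how the 2 sides were dissected stays open.

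The 444 calls themselves were set against other splits of the libraries. Among 100 splits (all 16 that put 1 library of each animal on each side, and 84 drawn from the others), 1, the real one, gave 444 or more. The 84 part only 1 or 3 animals, so they are not comparable with the real split in a paired test and do not bear on chance. The highest other count was 389, from a split that kept the true sides in animals 1, 2 and 4 and left animals 3 and 5 undivided. Among the drawn splits 277 came next, with the true sides kept in animals 1, 2 and 3. Every other drawn split gave 2 or fewer. Among the 16 splits that part every animal, the real one gave 444 and the highest other 286, from the split that turns round animal 5 alone. Each of the rest gave 0. Even so, 16 splits are too few for a share under 0.05. Depth between the sides is argued against, as the ipsilateral library was the deeper in 2 of 5 animals while 97.3% of called genes moved the same way in all 5. Reads divided between similar genes are argued against as the whole cause, since 86.0% of called genes had whole counts in all 10 libraries (87.4% of tested genes). The median change of the called genes kept at least 96.6% of its size in every animal after the length trend was removed. That argues against the trend as the whole cause. After the axes that separate the animals were removed, it kept at least 82.9%. So most of the median change of the called genes lay off those axes. The axes held 0.876% to 7.12% of the variance of the side differences. That share is over all tested genes, noise included, and says little about the called ones. A difference between the sides in tissue makeup or dissection that lies off those axes was not tested. The second correction lowered the number of calls in limma on the side differences from 420 to 244, so a part of the calls may rest on those axes. Right against left cannot be told apart from injury, because the ipsilateral side was the right in 5 of 5 animals.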

How the results depend on the processing

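DESeq2 and limma-voom without the block, and the limma fits on side differences, were chosen after seeing the data. Each of the 444 called genes kept its direction in every setting that tested it, the fit without the replicate block included. As 432 of them moved the same way in all 5 animals and the settings share the same libraries, this is little evidence of robustness. Of the 444, 8 were not tested under the stricter filter, 2 with the length trend removed, and 1 each without animals 3 and 4. The count was within 1.5 times of 444 under RLE (418) and upper-quartile scaling (411), the stricter filter (419), no filter (621), DESeq2 (474), limma-voom (438), the non-robust fit (434), limma on side differences (420) and the same with the length trend removed (396), and with animal 3 left out (307). Of these calls, 407 with RLE, 361 with DESeq2 and 389 with limma-voom were shared with the 444. Without the replicate block the counts were 0 in edgeR (0 higher, 0 lower), 0 in limma-voom (0 and 0) and 13 in DESeq2 (10 and 3), so the calls rest on the paired comparison. On the deposited TPM, limma-trend called 43 genes (33 and 10) at a pseudocount of 1 and 76 (65 and 11) at 0.1. These 2 fits used no TMM scaling and tested 20065 genes. The cause of the lower counts was not tested. With the axes between animals removed, limma on side differences called 244 (214 and 30) in place of 420 (363 and 57), 212 of them among the 444. The genes that fell numbered 128 with no filter. In limma on side differences they numbered 57 with nothing removed and 51 with the length trend removed. Leaving out each animal gave 135 to 1255 genes (123 to 773 higher and 12 to 482 lower): 135 without animal 1, 196 without animal 2, 206 without animal 4 and 1255 without animal 5, where the share of higher genes was 61.6% in place of 82.0%; 270 of the 307 genes called without animal 3 and 431 of the 1255 without animal 5 were among the 444. Under the scalings the share of higher genes was 78.5% and 81.0%. The 4 named genes kept their direction in each setting in which they were tested. They had been chosen for moving the same way in 5 of 5 animals. ENSMFAG00000005215 passed the threshold in 18 of 20 alternatives, ENSMFAG00000060234 in 13 of 20, ENSMFAG00000036097 in 10 of 18 and ENSMFAG00000028239 in 8 of 19. Alternatives for the gene lists were not run, since the lists were not tested. How depth limits the calls was not tested; 1.09% of the least abundant of the 4 classes were called.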

Other observations

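Some genes differed between animals by more than 8-fold and did so on both sides. In animal 3, 171 of the tested genes were at least 8-fold lower, and 9 at least 8-fold higher, in both libraries than in each of the other 8. The counts were 4 lower and 1 higher in animal 2, 2 lower and 0 higher in animal 4, and 0 in either direction in animals 1 and 5. Of the 180 such genes of animal 3, 11 were also called between the sides.

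Both libraries of animal 5 lay at the low end of the third component (-30.1 contralateral and -31.3 ipsilateral), the direction in which the ipsilateral side moved in the other 4 animals, whose ipsilateral scores were -6.74 to 6.65. A hypothesis, formed after seeing this, is that both sides of animal 5 carry part of the side difference of the other animals, so that little of it shows between them. The profile of animal 5 minus that of animals 1, 2 and 4 correlated across genes with the mean side difference of those 3 at r = 0.19. When animals 1, 2 and 4 took its place, the correlation was -0.10 to -0.01. Animal 5 was then part of the reference, so these values are no independent baseline for the 0.19. With animal 3 among the others, the correlation for animal 5 was -0.01, while animal 3 itself, which does show the side difference, correlated at 0.19 with that of its 4 others, so such a value is not particular to animal 5. The value turns on animal 3 and rests on 1 animal, so the hypothesis stays open.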
